A study of Rattus norvegicus with 8 samples.

How the data were processed

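RNA of the ventral prostate of Sprague-Dawley rats was measured on 8 Affymetrix expression arrays in 4 groups of 2. The groups were whole ventral prostate of control and of vinclozolin lineage males at 180 days of age, and prostate epithelium of control and of vinclozolin lineage males at 45 days. Groups were taken from the sample titles. The treatment protocol of all 8 samples, those titled vinclozolin included, names injection of the vehicle (DMSO). This conflict in the labels was left as it stands, and every statement on vinclozolin rests on the titles. Each epithelium sample pooled 11 animals per the labels, and each whole prostate sample pooled several, with no number stated. The labels do not say whether the 2 samples of a group came from separate animals, so p-values measure the spread between these pooled samples, which may be partly technical.

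The deposited values are probe set intensities on a linear scale, for 31099 probe sets. The software that made them is not given in the sources used here. From the values, every array had the same 2% trimmed mean of about 125 intensity units, so the authors had put the arrays on a common mean. The array medians still ranged from 28.7 to 38.7. Labelling with biotin by the maker's standard procedure is stated per the labels' protocols.

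Intensities were taken to log2(value + 16). The medians of the arrays then differed by up to 0.29, more than the 0.2 allowed before the data were examined, so the arrays were quantile normalised. The 57 control probe sets were left out first. Probe sets with a mean under the 30th percentile were then left out, which kept 21729. Because of the added 16, fold changes of dim probe sets are understated. Of the probe sets, 20832 had 1 gene symbol in the platform annotation, 436 had several and 9780 non-control ones were not listed with a gene. Genes were named only from probe sets with 1 symbol. The Entrez identifiers of 20764 probe sets were found in the RefSeq table of assembly GRCr8, and 0 symbols needed an update. Chromosome and start of genes were taken from that table only to order them for the test of neighbouring genes.

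Group means of all 8 arrays were fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with 4 residual degrees of freedom and an estimated prior of 2.62. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The comparisons were vinclozolin against control in whole prostate, the same in epithelium, the difference of these effects, and control epithelium against control whole prostate. Python 3.11.15 was used to read the tables and matplotlib 3.10.9 to draw the plots.

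Before the data were examined, 42 gene lists were fixed, 27 of pathways and 15 of cell types. Of their 1382 entries, 1230 (89.0%) matched a gene on the array. Lists were tested with camera of limma at a preset correlation of 0.01, on the brightest probe set of each gene, for the 40 lists with at least 5 measured genes. The granulocyte and red blood cell lists had 4 measured genes each and were not tested. Camera with an estimated correlation and fry were alternatives. At the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes the 4 residual ones of the arrays. P-values at the preset correlation thus rest on genes, not on arrays, as replicates. Where the members of a list are counted, the count over all probe sets tested is given first, and where stated also the count adjusted over the list alone.

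Genes named in the text were chosen by a rule fixed before the data were examined. For each vinclozolin comparison it takes, among called probe sets with 1 symbol whose arrays do not overlap between the groups, the 12 that rose and the 12 that fell most, with 1 probe set per gene, the one of lowest p. Where fewer were called, the lowest unadjusted p fill up to 6 per direction and are given as not passing. It adds up to 4 members of lowest p per list, and Msmb, Fas, Pbsn, Clu, Mki67, Krt8, Krt5, Acta2, Dnmt1 and Dnmt3a in every comparison. Other genes fixed by that rule are not reported here. For the difference of effects it takes 6 genes per direction, and for the control groups the 5 most changed per direction and the list members. Names outside the rule are said to be so.

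The fit was tested on simulated data for 21729 probe sets with measured group means. The spread of each was drawn from the prior that limma had fitted, whatever its intensity, with independent normal errors. The assumptions of the fit thus held by construction, so the false calls below do not test departures from them. In the simulated whole prostate comparison, 25% of 100 probe sets changed by 1 log2 unit and 85% of 100 changed by 2 were called, with 8 false calls among 118. In the simulated epithelium comparison the shares were 29% and 87%, with 5 false calls among 121. A simulated shift of 0.5 in 1 of 40 lists was called, with 0 calls among the lists that share no gene with it. The number of arrays limits the precision. An exact test of 2 arrays against 2 cannot give a two-sided p under 0.33, so no such test was run.

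Alternatives were other pseudocounts (1 and 64), the values as deposited, median centring, no filter and a filter at the 50th percentile, a trended robust prior, array weights, a replicate block, other thresholds, a fit of the 4 arrays of a comparison, and leaving out each array. The labelled arrays were all distinct, and the highest share of equal values between any pair of arrays was 0.611%.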

Results

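Vinclozolin is an agricultural fungicide with antiandrogenic activity. Pregnant rats of the founder generation were injected intraperitoneally from day 8 to day 14 of gestation, and tissue was taken from males of generation 3. The question was whether the prostate transcriptome of such descendants differed from that of control descendants. Gene expression was measured in whole ventral prostate at 180 days and in prostate epithelium at 45 days, with 2 control and 2 vinclozolin arrays each. Age and preparation changed together, so they cannot be separated. Values below are log2 changes, vinclozolin minus control, with the standard error (SE) of the fit and n = 2 arrays per group, on the log2(intensity + 16) scale. The treatment protocol names only the vehicle for all samples, so the groups are those of the titles. Between 28.3% and 36.8% of probe sets on an array had an intensity under 16. The median standard deviation between the arrays of a group was 0.10 and 0.12 in whole prostate control and vinclozolin, and 0.14 and 0.13 in epithelium control and vinclozolin.

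In whole ventral prostate of the vinclozolin lineage, interferon response and antigen presentation genes rose, skeletal muscle genes fell, and Msmb and Azgp1, which encode secreted proteins, fell. Fam111a, which encodes a nuclear protease with a role in DNA replication, rose the most of the named genes, by 6.61 ± 0.15, or 97.5-fold. Cyssl2 rose by 4.47 ± 0.17 (22.2-fold) on 1 probe set and by 0.79 ± 0.11 on its other. Usp18, which removes the interferon-induced ISG15 from proteins, rose by 2.41 ± 0.19. Cmahp fell by 3.62 ± 0.11, or 12.3-fold, and the fast skeletal myosin light chain genes Myl11 and Myl1 fell by 3.20 ± 0.43 and 2.87 ± 0.16. In limma's fit, 379 of 21729 probe sets were called, 178 higher and 201 lower, in 253 named genes.

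Further genes that rose were Ldoc1 (2.24 ± 0.14), Mcpt1l1, a member of the mast cell protease family (2.22 ± 0.15), Ocm, which encodes the calcium-binding protein oncomodulin (2.17 ± 0.12), Tmem59l (2.17 ± 0.20), Slc5a11, a sodium-dependent inositol transporter (2.15 ± 0.22), Uchl1, a ubiquitin hydrolase (1.98 ± 0.12), LOC102546992 (1.89 ± 0.21) and Ifi27l2b (1.88 ± 0.13). Further genes that fell, with log2 changes in brackets, were Fmo5, a flavin monooxygenase (-2.15 ± 0.12), Pdia5, a protein disulphide isomerase (-2.12 ± 0.15), Tpm1, a tropomyosin (-2.12 ± 0.16), and Csap1 (-1.84 ± 0.14). All 6 probe sets of Tpm1 had a negative change and 5 were called. The value of -2.12 is from 1 of them, and the rest lay between -1.13 and -0.93. Among calls, 210 changed at least 2-fold, 26 at least 4-fold and 9 at least 8-fold. The unnamed probe sets 1379497_at (7.12 ± 0.11) and 1398411_at (5.07 ± 0.14) were also among the 9, and they are named here after their values were seen.

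All 31 measured genes of the interferon response list had a positive change, and their median was 0.77. Of these, 10 were called higher and 0 lower, and 28 were higher when adjusted over the list alone. Ifi27 rose by 1.63 ± 0.11, Irf8, a transcription factor of myeloid cells, by 1.47 ± 0.11, and Oas1a, a sensor of double-stranded RNA, by 1.23 ± 0.13. The list rose against all other genes (camera adjusted p = 7.0e-22), and it held with an estimated correlation (adjusted p = 0.026). Mx2, an interferon-induced GTPase, had probe sets that disagreed, since 1 fell by 3.01 ± 0.26 while the other rose by 1.13 ± 0.14, and both were called.

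Antigen presentation genes rose with a median of 0.66 over 23 genes (camera adjusted p = 6.1e-08, and adjusted p = 0.039 with an estimated correlation). RT1-Ba, RT1-S3 and RT1-Da of the major histocompatibility complex and Cd74, the invariant chain, were the 4 called, and 11 were higher when adjusted over the list alone. RT1-S3 rose by 1.54 ± 0.22 and Cd74 by 1.03 ± 0.13. RT1-Ba rose by 2.25 ± 0.19 on 1 of its 4 probe sets, and the other 3 were not called, at 0.21, 0.41 and -0.54. RT1-Bb fell by 3.02 ± 0.29 on 1 probe set, while its other probe set measured 1.21 ± 0.29 and was not called (adjusted p = 0.095).

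Markers of leukocytes moved with these groups. Macrophage markers rose with a median of 0.61 over 18 genes, 3 called higher (camera adjusted p = 0.00071, and adjusted p = 0.10 with an estimated correlation). Fcgr3a, an Fc receptor, rose by 1.17 ± 0.19 and Csf1r, the receptor of colony stimulating factor 1, by 1.11 ± 0.15, whereas Lyz2, the lysozyme of macrophages, measured -0.86 ± 0.16 and was not called. T and NK lymphocyte markers rose with a median of 0.62 over 14 genes, 0 called singly (camera adjusted p = 0.00011, and adjusted p = 0.095 with an estimated correlation). Inflammatory cytokines and chemokines rose with a median of 0.24 over 47 genes (adjusted p = 0.0066, and 0.11 as the adjusted p with an estimated correlation). In that list Cxcl13, a chemokine for B cells, rose by 1.31 ± 0.21 and Cxcl11 by 1.03 ± 0.17, the 2 called. B and plasma cell markers (median 0.30, adjusted p = 0.095) and mast cell markers (median 0.06, adjusted p = 0.69) did not pass.

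Skeletal muscle genes fell, with a median of -1.16 over 20 genes, 7 called lower and 0 higher (camera adjusted p = 2.7e-13, and adjusted p = 0.039 with an estimated correlation). Tnnc2, fast troponin C, fell by 1.95 ± 0.11, Tnnt3 by 1.59 ± 0.18 on 1 of 2 probe sets (0.31 on the other, not called) and Acta1, skeletal alpha-actin, by 1.00 ± 0.10. Adjusted over the list alone, 16 fell. Tnnc2 had a mean of 9.47 in epithelium control and 8.53 in whole prostate control, whereas Myl1 had 5.18 and 8.55. Smooth muscle genes also fell, with a median of -0.27 over 20 genes (camera adjusted p = 0.0055, and adjusted p = 0.12 with an estimated correlation). Of these, 0 were called on the brightest probe set, though Tpm1, a member, was called lower on 5 of 6 probe sets.

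RNAs of several secreted proteins were lower. Azgp1, zinc-alpha-2-glycoprotein, fell by 2.10 ± 0.15, Msmb, beta-microseminoprotein, by 1.55 ± 0.11, and the seminal vesicle secretion gene Svs4 by 1.17 ± 0.12. The list of ventral prostate secretory proteins had 4 of 19 genes called lower and 0 higher. Adjusted over the list alone, 5 were lower and 2 higher. Its test gave a fall (camera adjusted p = 0.026) although its median was only -0.04 and its mean -0.34. That call was lost with the values as deposited (median 0.02), with median centring and with an estimated correlation (adjusted p = 0.16). Genes for proteins of other sex accessory glands, a list that shares Msmb and Svs4, fell with a median of -0.49 over 10 genes. The camera adjusted p of that list was 0.0055, and 0.12 with an estimated correlation. The androgen-responsive list did not shift (median 0.02, adjusted p = 0.96). In it Azgp1 and Eaf2, an elongation factor partner (-1.29 ± 0.11), fell, while Cdkn1a, a cell cycle inhibitor (0.87 ± 0.13), and Abhd2 (0.71 ± 0.12) rose. Pbsn, probasin, measured -0.31 ± 0.11 and was not called (adjusted p = 0.20).

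The immediate early transcription factor genes Fos (-1.92 ± 0.12), Egr1 (-1.49 ± 0.12) and Fosb (-0.85 ± 0.10) fell and Rgs2 rose (0.71 ± 0.11), while their list of 35 genes did not pass (median -0.20, adjusted p = 0.48). Among growth factors, Bmp6 fell by 1.97 ± 0.23 and Fst, follistatin, by 1.13 ± 0.18 on 1 of 2 probe sets, with no shift of the list (adjusted p = 0.35). Clu, the chaperone clusterin, rose by 1.00 ± 0.13 on 1 of 2 probe sets. Endoplasmic reticulum folding genes rose slightly (median 0.15 over 44 genes, 1 called, camera adjusted p = 0.00093, and adjusted p = 0.10 with an estimated correlation), as did cell cycle genes (median 0.25, 0 called, adjusted p = 0.031, and adjusted p = 0.16 with an estimated correlation) and oxidative phosphorylation genes (median 0.09, 0 called, adjusted p = 0.026, and adjusted p = 0.27 with an estimated correlation). Luminal markers (median -0.09, adjusted p = 0.52), basal markers (median 0.08, adjusted p = 0.51), fibroblast markers (median -0.08, adjusted p = 0.80), Wnt signalling genes (median 0.01, adjusted p = 0.77), calcium signalling genes (median -0.06, adjusted p = 0.66) and DNA methylation and chromatin enzymes (median -0.11, adjusted p = 0.16) did not pass. Fas (-0.51 ± 0.17), Krt8 (0.28 ± 0.12), Krt5 (0.60 ± 0.11), Acta2 (0.32 ± 0.17), Mki67 (0.29 ± 0.25), Dnmt1 (-0.11 ± 0.15) and Dnmt3a (-0.09 ± 0.31) were not called.

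Both arrays of a group lay apart from both of the other for 53.9% of probe sets in whole prostate, against 33.3% by chance, and 4067 had an unadjusted p under 0.05. Across probe sets, vinclozolin replicate 1 had a Spearman correlation of 0.9308 with control replicate 2 and of 0.9274 with vinclozolin replicate 2, which had the lowest correlations with the controls (0.9177 and 0.9221). The count of calls was 32 and 26 without whole prostate control replicate 1 and 2, 57 and 50 without vinclozolin replicate 1 and 2, 220 without either epithelium control and 199 without either epithelium vinclozolin array. With median centring 178 were higher and 315 lower, and the call of Myl11 was lost with any whole prostate array left out (adjusted p from 0.078 to 0.18). As a sign of RNA quality, the 3' to 5' ratio of the beta-actin control probe sets was 3.74 and 3.98 on the whole prostate control arrays and 3.37 and 3.14 on the vinclozolin arrays. The control probe set of 5S ribosomal RNA read 463 and 479 on the former and 189 and 184 on the latter.

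**Figure D1:**
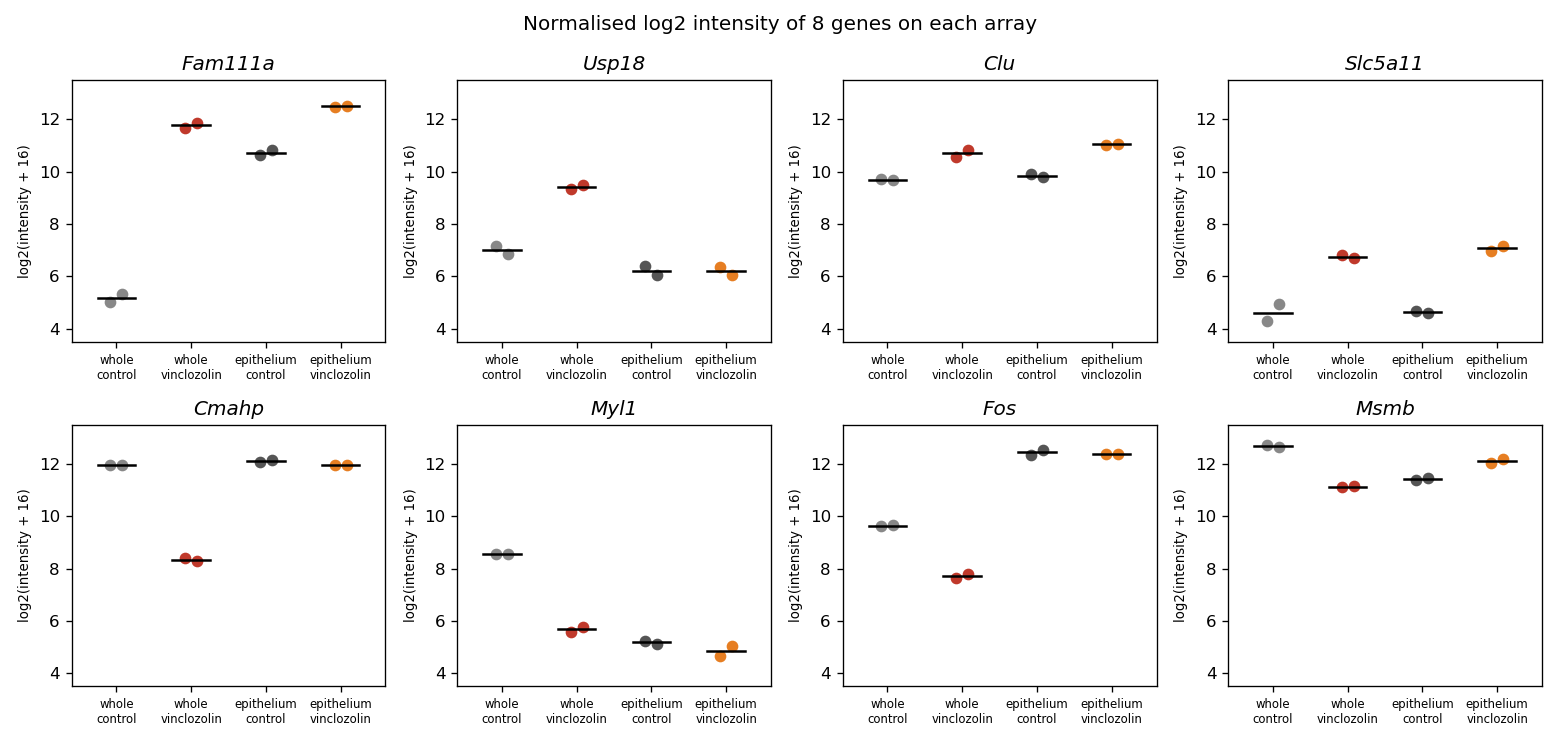
Normalised expression, log2(intensity + 16), of 8 genes on each of the 8 arrays, by group. Points are arrays, black lines are group means, and Fam111a lies near 5.2 in whole prostate control and at 10.6 or above on the arrays of the other groups, and Msmb is lower with vinclozolin in whole prostate but not in epithelium.

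In epithelium, no named gene passed the test, and 2 unnamed probe sets did. Probe set 1385146_at rose by 1.62 ± 0.11 and 1381127_at fell by 2.23 ± 0.14, both with an adjusted p of 0.0287. The genes with the lowest p and a positive change, given as values that did not pass, were Fam111a (1.77 ± 0.15) and Trak2 (1.38 ± 0.12), a mitochondrial trafficking adaptor. They were followed by Slc5a11 (2.45 ± 0.22), the carbohydrate kinase Fggy (1.20 ± 0.11), Akr1c13, an aldo-keto reductase (1.28 ± 0.13), and Clu (1.21 ± 0.13), with adjusted p from 0.063 to 0.11. Those with a negative change were Hsd17b6, a hydroxysteroid dehydrogenase (-1.22 ± 0.11), Zfp212 (-1.47 ± 0.15), Cc2d1a (-1.34 ± 0.15), Lgals3, galectin 3 (-0.93 ± 0.11), Cyp1a1, a cytochrome induced by aryl hydrocarbons (-1.72 ± 0.20), and Card14 (-1.79 ± 0.21), with adjusted p from 0.067 to 0.11. Trak2, Clu, Zfp212 and Cc2d1a each had another probe set, at 0.14, 0.53, -0.66 and -0.13.

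Gene lists in epithelium moved by less than 0.40 in the median, and each of the 8 calls at the preset correlation was lost with an estimated one. The estimated correlations of these 8 lists, from -0.050 for clock genes to 0.0058 for endoplasmic reticulum folding genes, lay under the preset 0.01. A higher correlation was therefore not the reason for the loss. Immediate early genes fell (median -0.18 over 35 genes, camera adjusted p = 0.00027, and adjusted p = 0.18 with an estimated correlation), with Gadd45b at -0.99 ± 0.12. Cell cycle genes rose (median 0.27 over 35 genes, adjusted p = 0.0010, and adjusted p = 0.18 with an estimated correlation). Genes for proteins of other sex accessory glands rose (median 0.39 over 10 genes, camera adjusted p = 0.0018, and 0.18 with an estimated correlation). Among them Msmb measured 0.70 ± 0.11 and Svs4 0.59 ± 0.12. Endoplasmic reticulum folding genes rose (median 0.11, adjusted p = 0.0029, and adjusted p = 0.18 with an estimated correlation). Smooth muscle genes (median -0.16, adjusted p = 0.017), inflammatory cytokines and chemokines (median -0.18, adjusted p = 0.020), heat shock proteins (median -0.15, adjusted p = 0.028) and clock genes (median -0.17, adjusted p = 0.037) fell. With an estimated correlation the adjusted p of these was 0.19, 0.19, 0.21 and 0.23 in that order. Over all genes tested, 0 members of these lists were called. The interferon response list (median 0.09, adjusted p = 0.49), the skeletal muscle list (median -0.11, adjusted p = 0.46) and the luminal list (median -0.06, adjusted p = 0.24) did not pass, nor did Fas (-0.58 ± 0.17), Pbsn (0.23 ± 0.11), Krt8 (-0.12 ± 0.12), Krt5 (0.10 ± 0.11), Acta2 (-0.13 ± 0.17), Mki67 (0.27 ± 0.25), Dnmt1 (-0.22 ± 0.15) or Dnmt3a (0.11 ± 0.31).

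In epithelium 2471 probe sets had an unadjusted p under 0.05, and groups lay apart for 39.4% against 33.3% by chance. The Spearman correlation of control replicate 2 was 0.9316 with vinclozolin replicate 2 and 0.9273 with control replicate 1. The 2 calls in limma became 0 with array weights, a pseudocount of 1, no filter, the 4 arrays alone, or any array left out, and 205 with a trended robust prior.

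**Figure D2:**
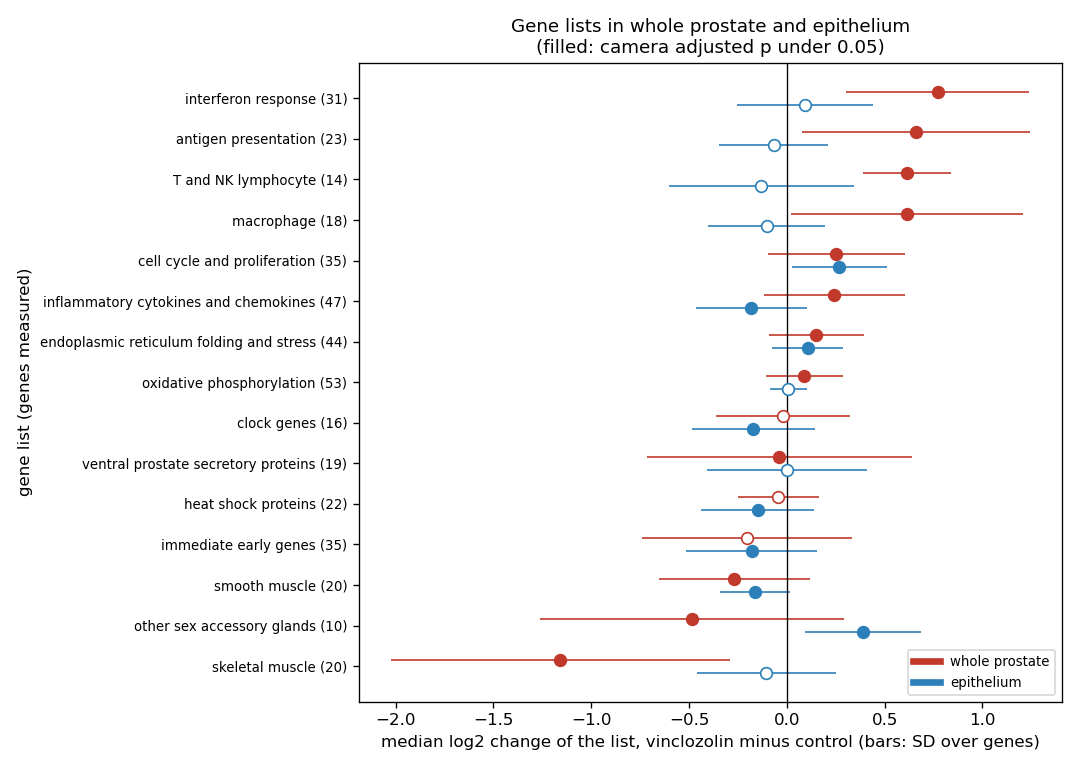
Median log2 change, vinclozolin minus control, of 15 gene lists in whole prostate and in epithelium. Bars are the standard deviation over genes, filled points mark camera adjusted p under 0.05 at the preset correlation, and the interferon response list lies at 0.77 in whole prostate and 0.09 in epithelium, and the skeletal muscle list at -1.16 and -0.11.

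The effects in the 2 tissues were compared directly. Changes in epithelium exceeded those in whole prostate for Cmahp (difference 3.49 ± 0.15), Car2, a carbonic anhydrase (2.40 ± 0.16), Msmb (2.25 ± 0.16), Akr1c13 (2.21 ± 0.19), Gstm6l, a glutathione transferase (2.18 ± 0.16), and Atp6v1c2, a proton pump subunit (2.13 ± 0.18). They were below those in whole prostate for Fam111a (-4.84 ± 0.22), Cyssl2 on 1 of 2 probe sets (-4.68 ± 0.24), Ocm (-2.62 ± 0.17), Ldoc1 (-2.55 ± 0.19), Mcpt1l1 (-2.24 ± 0.21) and Ifi27 (-1.61 ± 0.16). The difference was called in limma for 63 probe sets, 37 positive and 26 negative, with adjusted p of 0.0201 or lower for these 12 genes. Fam111a and that probe set of Cyssl2 were low only in whole prostate control, so their differences rest on that group. The interferon response list (median -0.72), the antigen presentation list (median -0.56) and the skeletal muscle list (median 1.24) differed between the tissues, and all held with an estimated correlation (adjusted p = 0.040). The count of 63 was 5 without either whole prostate control replicate or without vinclozolin replicate 1, 10 without whole prostate vinclozolin replicate 2, 12 and 18 without epithelium control replicate 1 and 2, and 12 and 6 without epithelium vinclozolin replicate 1 and 2.

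Clu was higher by 1.00 ± 0.13 in whole prostate, where it was called, and by 1.21 ± 0.13 in epithelium, where it was not, on 1 of 2 probe sets. The other probe set of Clu measured 0.14 and 0.53 and was not called. On the former the difference of effects was 0.20 ± 0.19 (adjusted p = 0.69). Across all probe sets, which are not independent replicates, the log2 changes in the 2 tissues correlated weakly (Pearson 0.092, Spearman 0.097). Of the 379 calls in whole prostate, 247 (65.2%) had the same sign in epithelium, as did 54.2% of all probe sets. At an unadjusted p under 0.05, 239 probe sets were higher in both (106 for independent lists), 252 lower in both (125) and 246 opposite (231). Only 1381127_at was called in both tissues, lower in each.

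Between the control groups, 45-day epithelium had higher immediate early, chemokine, matrix, basal and smooth muscle genes and lower adipocyte and macrophage genes than 180-day whole prostate. The neutrophil chemokine Cxcl1 was higher by 6.31 ± 0.32, Fam111a by 5.57 ± 0.15, Cyssl2 by 5.35 ± 0.17 (0.48 on its other probe set), the stress-induced factor Atf3 by 5.17 ± 0.22 and the chemokine Ccl20 by 4.88 ± 0.15. Lpl, lipoprotein lipase (-3.95 ± 0.14), Cfd, adipsin (-3.78 ± 0.14), Myl11 (-3.43 ± 0.43), Adipoq, adiponectin (-3.38 ± 0.16), and Myl1 (-3.37 ± 0.16) were lower. Of 35 immediate early genes, 30 were called higher and 0 lower (median 2.46, camera adjusted p = 1.7e-27), with Fosb at 4.70 ± 0.10 and Egr1 at 3.80 ± 0.12. Of 47 inflammatory cytokines and chemokines, 18 were called higher and 8 lower (median 0.41, camera adjusted p = 0.00027, and adjusted p = 0.042 with an estimated correlation). The 3' to 5' ratio of the beta-actin control probe sets was 2.57 and 2.27 on the epithelium control arrays, against 3.74 and 3.98 on the whole prostate control arrays, and that of Gapdh was 1.08 and 1.13 against 1.47 and 1.39.

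In the samples labelled epithelium, matrix, smooth muscle, fibroblast, endothelial and basal markers were higher, and adipocyte, macrophage and mast cell markers were lower. Extracellular matrix genes were called higher in 37 of 51 and lower in 3 (median 1.04, Col1a1 3.13 ± 0.13), smooth muscle genes in 12 of 20 and lower in 2 (median 1.62, Acta2 3.65 ± 0.17), fibroblast genes in 11 of 20 and lower in 3 (median 0.67) and basal genes in 9 of 13 and lower in 1 (median 1.20, Krt5 2.40 ± 0.11, Krt17 3.96 ± 0.14). Cell cycle genes were called higher in 23 of 35 (median 0.99, Mki67 2.38 ± 0.25). Endothelial markers were called higher in 8 of 18 and lower in 1 (median 0.43, camera adjusted p = 0.0023). With an estimated correlation their adjusted p was 0.062. Luminal markers did not shift (median -0.05, camera adjusted p = 0.70). Among them Krt8 was higher by 0.62 ± 0.12, and Tmprss2, a serine protease of luminal cells, was lower on 1 of 2 probe sets (-1.24 ± 0.16). Luminal enrichment was therefore not seen in these samples, and the name epithelium rests on the titles. Adipocyte genes were called lower in 11 of 14 (median -1.90) and macrophage genes in 10 of 18 (median -0.96). The matrix, smooth muscle, fibroblast, basal, cell cycle, adipocyte and macrophage lists held with an estimated correlation, with adjusted p from 0.017 to 0.047. Mast cell markers were lower (median -0.68, camera adjusted p = 0.025, and adjusted p = 0.12 with an estimated correlation). Msmb was lower (-1.25 ± 0.11), Dnmt1 higher (0.72 ± 0.15), and Pbsn (-0.29), Clu (0.15) and Fas (0.01) were not called. Dnmt3a was not called on 1 probe set (0.16) and was higher on the other (1.35).

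In all, 6051 probe sets were called between the control groups in limma, 2801 higher and 3250 lower. This split depended on the scaling, with 3504 higher and 3013 lower in the values as deposited and 2246 higher and 5536 lower with median centring, where the median of all probe sets was -0.20. Leaving out whole prostate control replicate 1 or 2 gave 2661 and 2749 calls.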

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

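The tests of leukocyte share on bright genes and of muscle tissue share were chosen only after the results were seen. Each result here was singled out because the vinclozolin effect differed between epithelium and whole prostate in limma's test of the difference (epithelium minus whole, log2). That held for 63 probe sets. Positive differences were measured for Cmahp (3.49), Myl1 (2.55), Car2 (2.40), Msmb (2.25), Akr1c13 (2.21), Gstm6l (2.18), Csap1 (2.17) and Atp6v1c2 (2.13). Smaller positive ones were those of Tpm1 on the probe set that fell most in whole prostate (2.09), Fos (1.84), Fmo5 (1.80), Tnnc2 (1.64) and Fggy (1.48). Negative differences were measured for Fam111a (-4.84), Cyssl2 (-4.68), Ocm (-2.62), RT1-Ba (-2.59), Ldoc1 (-2.55), Usp18 (-2.45), Mcpt1l1 (-2.24), Tmem59l (-2.19), Ifi27 (-1.61) and Uchl1 (-1.33). Gene lists also differed by camera, here with their median differences, for skeletal muscle (1.24), other sex accessory glands (0.84), ventral prostate secretory proteins (0.058), apoptosis (-0.16), inflammatory cytokines and chemokines (-0.34), antigen presentation (-0.56), macrophage (-0.62), interferon response (-0.72) and T and NK lymphocyte (-0.77). The ventral prostate secretory list had 2 members called and a mean of 0.42. Of these lists, skeletal muscle, antigen presentation and interferon response held with an estimated correlation. The others had adjusted p from 0.061 to 0.18 with one.

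The largest change of a named gene in whole prostate was that of Fam111a, at a mean of 5.16 in whole prostate control and 11.77, 10.73 and 12.49 in the other groups. Other probe sets that rose at least 8-fold were likewise low only in whole prostate control. In the same order of groups, 1379497_at had means of 6.21, 13.33, 12.58 and 12.74. Those of 1398411_at were 7.33, 12.40, 11.07 and 11.50, and of Cyssl2 6.77, 11.24, 12.11 and 11.91. Their rise, their difference of effects and their difference between controls all rest on the same low control arrays. The quantile normalisation is argued against as a source of the calls, since 99.7% of the 379 calls kept their direction and at least 80% of their change in the values as deposited. Those values had already been put on a common mean, so that earlier scaling was not tested. A variant of strain or family between the lines may be a source of part of the calls, and the bound set for it in advance was met, with 13 neighbouring pairs among 252 called genes against a random median of 5 (permutation p = 0.0027) and 10 pairs for as many genes of lowest p between the controls. The genes of lowest p in epithelium, where such a variant would act too, gave 11 pairs (permutation p = 0.0244). The 10 pairs between the controls (permutation p = 0.0512) limit what the 13 show. Related neighbours among the 13 were Ifi27 and Ifi27l2b, Mx1 and Mx2, and RT1-Ba and RT1-Bb. Others were Cyssl2 and Cyss, Ly6e and Ly6c, C2cd4b and C2cd4a, and Semg1 and Svs4. Random sets do not allow for related neighbours that change together, so meeting the bound does not single out a variant. A stricter requirement tried after the result was seen took the epithelium set as its baseline and decides nothing, and the treatment stays open beside the variant.

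Interferon response genes rose in whole prostate, and a single deviating array is argued against, since the highest camera adjusted p with any whole prostate array left out was 3.0e-17. A larger share of leukocytes was first tested over all genes, and 39 leukocyte markers (median 0.56) lay below 31 interferon genes (median 0.77) by a difference of -0.21 (one-sided permutation p = 0.00439 over genes, which are not independent), which argued against that share by the bound then set. After that result was seen, the test was restricted to genes at log2 7 or more, because 32 of the markers but 16 of the interferon genes lay below it, where the added 16 shrinks changes. There 7 markers had a median of 0.62 and 15 interferon genes 0.96, and the difference of -0.337 had a one-sided permutation p of 0.052. By the restricted test leukocyte share and interferon response cannot be told apart, because few markers are bright.

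Skeletal muscle genes fell in whole prostate, and vinclozolin lineage itself stays open as an untested biological explanation. A single deviating array is argued against (highest camera adjusted p 6.85e-10 with an array left out), and both control arrays had the same list mean of 6.84 against 5.55 and 5.61 with vinclozolin. A smaller amount of skeletal muscle tissue and lower expression in it cannot be told apart. Both assume that the list marks muscle, yet between the controls 4 of its 20 members were called higher in epithelium and 11 lower. Tnnc2 was brighter in epithelium control (9.47) than in whole prostate control (8.53), so its fall need not come from muscle. That 100% of the 7 members at log2 7 or more in controls were lower decides nothing, since 19 of the 20 members were already known to be lower. The changes of these 7 ranged from -0.28 for Myh1 to -3.20 for Myl11.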

How the results depend on the processing

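The count without certain gene lists, the interferon list without shared genes, and the lists on the 4 whole prostate arrays were chosen after seeing the data. Counts of calls changed with most settings. For whole prostate (379), epithelium (2) and the difference of effects (63), a pseudocount of 1 gave 235, 0 and 40, a pseudocount of 64 gave 1133, 66 and 262, no filter 200, 0 and 32, the 50th percentile filter 965, 23 and 169, a trended robust prior 1814, 205 and 540, an adjusted p under 0.10 1154, 9 and 189, and an unadjusted p under 0.05 with 1.5-fold 1669, 956 and 2067. Array weights gave 871 in whole prostate and 0 in epithelium, and median centring 1 in epithelium. The 4 arrays alone gave 65 and 0. With the replicate block the counts were 32, 0 and 5, a fit with fewer residual degrees of freedom, and between the controls 4537. Same-numbered arrays did not deviate together (correlation 0.0028 in whole prostate and 0.029 in epithelium), so no crossed block was run. With 1 replicate difference per group, this cannot exclude that the numbers mark shared animals or days. With 1 array left out, whose partner is assumed to vary like the other groups, counts ranged from 26 to 220 in whole prostate, 0 to 0 in epithelium, 5 to 18 for the difference and 2661 to 5751 between the controls. The cause of the other changes was not tested. Of the 379 calls, 364 were shared by the values as deposited (490 calls) and 376 or more kept their sign under each pseudocount and scaling. Of the same calls, 362 lie outside the skeletal muscle, antigen presentation and RT1 genes.

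The correlation of effects was 0.059 with no filter and 0.15 with the 50th percentile filter, and 0.059 to 0.099 with 1 array left out. Lists called in whole prostate, epithelium, the difference and between controls (12, 8, 9 and 21) became 3, 0, 3 and 11 with an estimated correlation and 22, 15, 14 and 34 with fry. Fry asks whether a list moves, not whether it moves more than other genes. With 1 array left out they ranged from 10 to 13, 3 to 9, 8 to 10 and 20 to 21. In the whole prostate comparison, the interferon, antigen presentation and skeletal muscle lists were called under every alternative run for lists. The interferon list without its shared genes had a median of 0.76 over 28 genes. The ribosomal protein list reversed, from a fall that was not called to a called rise, with the values as deposited (median 0.17 in whole prostate and 0.28 between controls) and with median centring (0.12 and 0.050). Of 679 values of named genes, 0 reversed, where a change of sign counts only if called in either setting. Of these values, 236 were called in the main fit, and only they could lose a call. In 11801 alternative fits of all of them, 608 lost and 372 gained a call. Among uncalled results, 27 gene values changed sign and 65 list tests changed direction. Where intensities lie near the added 16, changes are understated.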

Other observations

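The choice of genes in these paragraphs was made after their values were seen. Beside Fam111a and Slc5a11, a set of genes went the same way in whole prostate at 180 days and in epithelium at 45 days. Of the probe sets called in whole prostate, 29 were lower and 26 higher in epithelium too, at an unadjusted p under 0.01, and 25 were opposite. Independent lists would give 3.39, 2.95 and 6.33, but both tests use the same estimate of spread per probe set, which raises all these counts. Genes lower in both were Setd1b, a histone H3 lysine 4 methyltransferase (-1.66 in whole prostate and -0.95 in epithelium), Vwc2 (-1.60 and -1.25), Tbc1d1 (-1.48 and -0.66), Rasd1, a glucocorticoid-induced small GTPase (-0.98 and -0.91), and Lgals3 (-0.95 and -0.93). Genes higher in both were Gna14, a G protein subunit (1.25 and 0.82), Scel, sciellin (1.23 and 0.99), and Stat2, an interferon signalling factor, on 1 of 2 probe sets (0.96 and 0.58). In epithelium alone, none of these genes passed the adjusted test in limma.

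Most genes that went opposite ways were lower in whole prostate. Msmb measured -1.55 and 0.70, Svs4 -1.17 and 0.59, Semg1 -0.80 and 0.56, and Wfdc5 -1.43 and 0.83, in whole prostate and epithelium. Azgp1, which also encodes a secreted protein, was lower in whole prostate (-2.10) and measured -0.84 in epithelium. Car2 (2 probe sets) measured -1.63 and -1.55 in whole prostate and 0.77 and 0.92 in epithelium, and Bmp6 (2 probe sets) -1.97 and -1.29 against 1.11 and 0.71. Of 16 genes with 2 or more called probe sets in whole prostate, only Mx2 was called in both directions. The imprinted RNA H19 fell in whole prostate by 1.47 on the log2 scale and measured -0.08 in epithelium.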
